A study of Mus musculus with 20 samples.

How the data were processed

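RNA of flow-sorted viable CD4+ T cells was sequenced from stranded messenger RNA libraries in 20 samples, 10 with both Eomes alleles floxed and no Cre (WT) and 10 with CD4Cre (KO). Per the labels, each genotype came from a pool of 2 mice, naive cells were isolated by negative selection, and cultures had no polarizing cytokines. The deposited file held whole-number raw counts per gene and sample. The authors' processing notes name TopHat2 2.0.5, featureCounts, Subread 2.10.1, DESeq2 and the mm10 genome for making these counts. The order and role of these tools, the strand setting, the handling of reads that map to several places and the annotation release are not given in the sources used here.

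The table held 52635 Ensembl genes, of which 52402 had a symbol in the reference annotation (GENCODE M21, GRCm38). The other 233 took 0.0166% of the counts. Where 147 symbols were shared by several identifiers, genes were kept apart by identifier. Libraries with 26869444 to 55516660 counts were grouped by genotype and time (3 per genotype at 0 h and at 12 h, 4 at 24 h), and replicate numbers were not taken to pair samples. Intervals for counts are exact Poisson intervals at 95% and cover counting error only.

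Genes were tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16, after filterByExpr left 15411 genes and with TMM scaling, in one model of 6 group means with 14 residual degrees of freedom. The common biological coefficient of variation was 0.0873. The comparisons were KO with WT at each time, 12 h with 0 h and 24 h with 12 h within each genotype, and the differences between genotypes in these changes and in that from 0 to 24 h. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called. Log2 fold changes are given with their standard error (SE), and levels as mean and standard deviation (SD) of CPM. Lists of genes, 34 of biology and 14 of quality or other-cell markers, were tested with camera of limma 3.58.1 with a correlation between genes estimated per list, and with a preset one of 0.01 and with fry as alternatives. Shares of counts were compared by exact two-sided permutation tests, whose smallest p was 0.1 for 3 against 3 and 0.0286 for 4 against 4.

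The genes named were chosen by a rule set beforehand. In KO against WT these were called genes with groups that did not overlap and a mean of at least 5 CPM in one group, the 10 largest changes in each direction, and up to 3 per list by p. With fewer than 5 called in a direction, the 5 with the smallest p are given as values. Within WT it took 6 per direction and up to 4 per list, and for differences between genotypes the 6 smallest p per direction. Both ranked parts also asked for a mean of at least 5 CPM in one group. Unnamed gene models, pseudogenes and receptor gene segments were left out of the ranked part. The text gives a part of the genes so chosen, and some are not reported here.

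Alternatives were other size factors, library size alone, other filters, limma voom, DESeq2 1.42.0, a fit of only the groups compared, a replicate block, and leaving out each library in turn. After the data had been seen, further alternatives were added: removing from each library, within a time, a spline trend with 4 degrees of freedom in transcript length and GC content (known for 15376 of the tested genes), or either trend alone, testing without pseudogenes or protein-coding genes alone, and removing that trend without KO 0 h replicate 1. Reads shared between genes were estimated from words of 50 bases in the transcripts of 55450 genes, of which 1 in 16 was kept. A genome sequence was not used here.

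The tests were checked on simulated data made from these counts. Of 67 genes changed by a fold of 2, edgeR called 74.6% in KO against WT at 0 h, 74.6% at 12 h and 77.6% at 24 h, and 7, 9 and 10 unchanged genes were called. The simulated counts were drawn independently around the group means. They held no structure among the libraries of a group and no correlation between genes, so these figures are not error rates for the real libraries.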

Results

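Messenger RNA was measured in naive CD4+ T cells, cells that had not yet met antigen, from mice whose Eomes alleles were flanked by loxP sites. Eomes encodes eomesodermin, a T-box transcription factor of cytotoxic, natural killer and memory lymphocytes. The mice of the 10 KO samples also carried CD4Cre, a transgene that drives the Cre recombinase in T cells. Those of the 10 WT samples did not, so every comparison of KO with WT was also one of mice with and without this transgene. Cells were sampled before stimulation (0 h, 3 WT and 3 KO) and after 12 h (3 and 3) or 24 h (4 and 4) with antibodies to CD3 and CD28, which mimic the T cell receptor signal and its costimulation. The series title places the samples in a study of Eomes, mitochondrial function and the survival of pathogenic CD4+ T cells. The labels do not say clearly whether replicates were separate pools of mice, so the p-values measure only the spread between these samples, which may be technical.

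Total counts per library ranged from 26869444 to 55516660. At 0 h they were 28355773, 34734425 and 30104473 in WT replicates 1 to 3 and 32962593, 37279239 and 38470475 in KO. At 12 h they were 28837582, 26869444 and 42522186 in WT and 30409867, 33018536 and 32594485 in KO. At 24 h they were 32474403, 34186311, 40112164 and 34578699 in WT replicates 1 to 4 and 27905212, 36105708, 38658590 and 55516660 in KO. Levels are given as CPM, the counts of a gene scaled to the library total multiplied by the TMM factor of that library. These factors ran from 0.918 in KO 0 h replicate 3 to 1.039 in KO 24 h replicate 1. A first principal component over the 1000 most variable genes held 80.6% of the variance and ordered the libraries by time. The second held 16.1% and set 12 h apart from 0 and 24 h, and the third held 1.49% and separated KO from WT within 24 h.

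**Figure D1:**
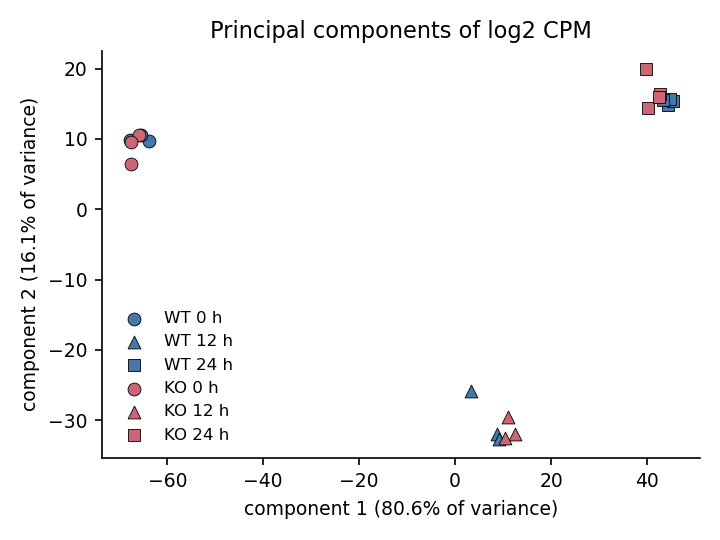
Scores of the 20 libraries on the first (x axis, 80.6% of variance) and second (y axis, 16.1%) principal components of log2 CPM over 1000 genes. Each point is a library, coloured by genotype and shaped by time, and the libraries group by time.

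Eomes (ENSMUSG00000032446, GRCm38 chromosome 9, 118478212 to 118486132) was lower in KO than in WT at every time. At 0 h, WT libraries held 152, 144 and 87 Eomes counts and KO libraries 11, 14 and 18, or 4.27 ± 1.15 and 0.418 ± 0.0823 CPM (SD, n = 3). This was a log2 fold change of -3.33 (SE 0.34, adjusted p = 1.11e-05). At 12 h the counts were 75, 60 and 92 in WT and 9, 7 and 17 in KO, or 2.28 ± 0.207 and 0.342 ± 0.157 CPM (SD, n = 3), with a log2 fold change of -2.72 (SE 0.37, adjusted p = 0.00111). At 24 h the counts were 129, 104, 110 and 132 in WT and 36, 51, 34 and 24 in KO, or 3.31 ± 0.563 and 0.970 ± 0.425 CPM (SD, n = 4), with a log2 fold change of -1.82 (SE 0.26, adjusted p = 1.05e-04). The lowest count, 7 in KO 12 h replicate 2, had an exact 95% Poisson interval of 2.81 to 14.4. Within WT, Eomes fell from 0 to 12 h (log2 fold change -0.91, SE 0.27, adjusted p = 0.00556), and the change from 12 to 24 h did not pass the test (0.54, SE 0.26, adjusted p = 0.0933). Within KO, it did not pass from 0 to 12 h (-0.29, SE 0.46, adjusted p = 0.590) and rose from 12 to 24 h (1.43, SE 0.38, adjusted p = 0.00328). Which part of the gene was deleted is not given in the sources used here, and the counts are of the whole gene.

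**Figure D2:**
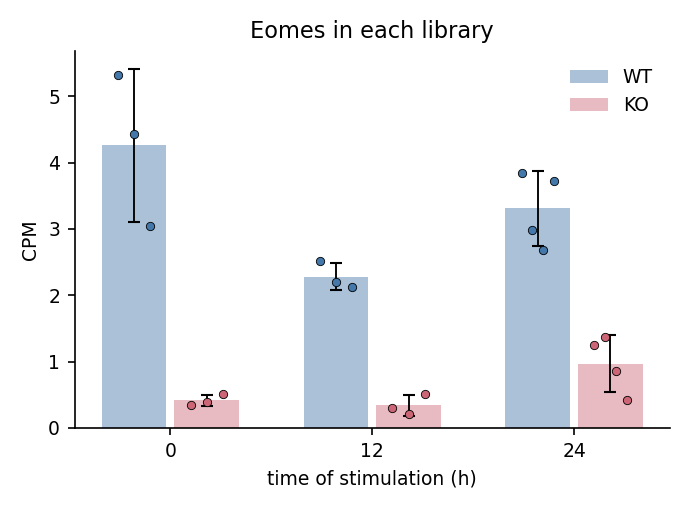
Eomes expression in CPM (y axis, from 0) by time and genotype (x axis). Bars are group means with SD and points are libraries, and the KO means of 0.418, 0.342 and 0.970 lie below the WT means of 4.27, 2.28 and 3.31 at 0, 12 and 24 h.

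The WT time course gives the changes after stimulation against which the genotypes were compared. No unstimulated culture was sampled at 12 or 24 h, so stimulation and time in culture cannot be told apart. From 0 to 12 h, genes of T cell activation rose steeply in WT. Il2ra, the high-affinity chain of the interleukin-2 receptor, went from 3.05 ± 1.42 to 396 ± 68.8 CPM (SD, n = 3), a log2 fold change of 7.01 (SE 0.20, adjusted p = 1.92e-18). Irf4, a transcription factor induced by T cell receptor signalling, went from 8.67 ± 1.12 to 1060.4 ± 235 CPM (SD, n = 3). The largest rises with counts at 0 h included Chst2, a sulfotransferase (log2 fold change 9.74, SE 0.31), the chemokine gene Xcl1 (9.63, SE 0.41), Akr1c18, a hydroxysteroid dehydrogenase (9.33, SE 0.22), and Bcat1, a branched-chain aminotransferase (9.25, SE 0.27). Bdh2, a short-chain dehydrogenase, had no counts in WT at 0 h and 38.1 ± 3.68 CPM at 12 h (SD, n = 3). Of 25 activation genes 20 rose and 1 fell, the same as adjusted over the list alone, with a median log2 fold change of 1.96 and adjusted p = 0.215 with an estimated correlation. Of 16 coinhibitory receptor genes 12 rose and 2 fell, also over the list alone (adjusted p = 0.233 with an estimated correlation), among them Lag3 (6.74, SE 0.17) and Pdcd1, which encodes PD-1 (5.06, SE 0.22).

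Genes of growth and biosynthesis rose together in WT between 0 and 12 h. All 28 MYC-associated genes of ribosome biogenesis rose, with the same count adjusted over the list alone, a median log2 fold change of 1.56 and adjusted p = 0.121 with an estimated correlation. Among them, Odc1, the first enzyme of polyamine synthesis, changed by 3.76 (SE 0.11, adjusted p = 3.09e-18) and Ncl, which encodes nucleolin, by 1.99 (SE 0.08). Of 20 genes of one-carbon metabolism and amino acid supply 19 rose (adjusted p = 0.121 with an estimated correlation), for example Shmt2, the mitochondrial serine hydroxymethyltransferase (2.31, SE 0.06). Of 25 genes of sterol and lipid synthesis 22 rose and 2 fell (adjusted p = 0.121 with an estimated correlation), for example Idi1 of the isoprenoid pathway (2.52, SE 0.12). Both counts were the same adjusted over the list alone. Among glycolytic genes, 14 of 21 rose and 6 fell, again also over the list alone (adjusted p = 0.283 with an estimated correlation), led by Hk2, a hexokinase that starts glycolysis (6.97, SE 0.25).

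Mitochondrial genes of the nucleus rose in WT by 12 h, while the transcripts of the mitochondrial genome did not rise with them. Of 84 genes of mitochondrial translation 68 rose and 5 fell (median 0.69), of 33 import and chaperone genes 30 rose and 1 fell (median 0.95), and of 36 subunits of respiratory complex I 23 rose and 3 fell (median 0.38). For these 3 lists adjusted p was 0.375, 0.233 and 0.644 with an estimated correlation. Complexes II to IV gave 20 higher and 1 lower of 24 (adjusted p = 0.514 with an estimated correlation), and the ATP synthase gave 12 higher of 16 (adjusted p = 0.547 with an estimated correlation). Of the 13 protein-coding genes of the mitochondrial genome, 1 rose and 7 fell (adjusted p = 0.705 with an estimated correlation), with mt-Co1, a subunit of cytochrome oxidase, at -0.60 (SE 0.07). These counts were the same adjusted over the list alone. The mitochondrial chaperone gene Hspd1 changed by 2.62 (SE 0.10) and Tomm40, the channel of the outer membrane import complex, by 2.01 (SE 0.07).

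Interferon-stimulated genes and naive-cell genes fell in WT by 12 h. Of 38 interferon-stimulated genes 36 fell and 1 rose, with the same counts adjusted over the list alone. Their median was -3.07, with adjusted p = 0.121 with an estimated correlation. Irf7, a regulator of the interferon response, changed by -3.81 (SE 0.13, adjusted p = 4.67e-17), Slfn5 by -3.84 (SE 0.16) and Ddx58, which encodes the RNA sensor RIG-I, by -2.77 (SE 0.09). Of 24 naive and quiescence genes 17 fell and 5 rose, also over the list alone, with adjusted p = 0.362 with an estimated correlation. Foxo1, which maintains naive T cells, changed by -1.62 (SE 0.09). Bach2, another transcription factor of the list, rose from 165 ± 20.9 to 708 ± 19.5 CPM (SD, n = 3). The largest falls were those of the monocarboxylate transporter gene Slc16a5, from 108 ± 5.53 to 0.637 ± 0.0580 CPM (SD, n = 3), and of P2rx7, a channel gated by extracellular ATP (-6.40, SE 0.28). Summed markers of other cells, not tested as sums, were lower at 12 h, among them Ctss-led macrophage and monocyte markers, from 264 to 86.7 summed CPM, and Ighm-led B cell markers, from 656 to 397. In all, 5409 genes were higher and 5233 lower of 15411 tested, and time and any day of preparation were the same split.

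From 12 to 24 h, transcripts of cell cycle genes rose in WT, and theirs was the only biological list called with an estimated correlation. Of 39 genes of DNA replication and mitosis 38 rose and 1 fell, with the same counts adjusted over the list alone, a median log2 fold change of 3.21 and adjusted p = 1.69e-06 with an estimated correlation. Mki67, a marker of cycling cells, went from 3.93 ± 1.27 (n = 3) to 607 ± 47.1 CPM (SD, n = 4), a log2 fold change of 7.31 (SE 0.30, adjusted p = 1.21e-15). Rrm2, a ribonucleotide reductase subunit needed for DNA synthesis, changed by 5.72 (SE 0.10, adjusted p = 2.36e-21) and Bub1, a kinase of the mitotic checkpoint, by 6.12 (SE 0.14). Pclaf, which binds the replication clamp, changed by 7.36 (SE 0.17), E2f8 by 7.03 (SE 0.17) and Esco2, needed for sister chromatid cohesion, by 7.14 (SE 0.16). Some of the cycle list had risen earlier, with 29 of its 39 genes higher and 4 lower at 12 h than at 0 h (31 and 4 adjusted over the list alone, adjusted p = 0.121 with an estimated correlation), such as Mcm5 of the replicative helicase (2.96, SE 0.08).

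Fuel metabolism and naive-cell genes also moved in WT between 12 and 24 h. Of 21 glycolytic genes 19 rose and 0 fell, among them the lactate transporter Slc16a3 (2.58, SE 0.13) and the enzyme Tpi1 (1.58, SE 0.09). Of 19 genes of mitochondrial fatty acid oxidation 15 rose and 1 fell, among them Acadl (1.22, SE 0.08). Adjusted p was 0.259 for the first list and 0.599 for the second with an estimated correlation. Of 24 naive and quiescence genes 22 fell and 2 rose (adjusted p = 0.279 with an estimated correlation), for example Il7r, the interleukin-7 receptor needed for naive T cell survival, from 502 ± 129 to 167 ± 9.33 CPM. S1pr1, which lets T cells leave lymphoid organs, changed by -1.53 (SE 0.11). Of the 13 protein-coding genes of the mitochondrial genome 11 fell and 0 rose (adjusted p = 0.599 with an estimated correlation), with mt-Nd4, a complex I subunit, at -0.53 (SE 0.07). These 4 pairs of counts were the same adjusted over the list alone. Of 36 complex I genes 8 rose and 1 fell (4 and 0 adjusted over the list alone), with adjusted p = 0.998 with an estimated correlation. The largest falls included Maf, a transcription factor of helper T cells (-2.66, SE 0.13), and Akr1c18 (-2.91, SE 0.11), which had risen by 12 h. In all, 4014 genes were higher and 3342 lower.

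The same 2 intervals were tested within KO. From 0 to 12 h, 5438 genes were higher and 5497 lower, and 9704 were called in the same direction in both genotypes and 0 in opposite directions. Across the 15411 genes, which are not independent replicates, the log2 fold changes of WT and KO had a Pearson correlation of 0.936. From 12 to 24 h, 4375 genes were higher and 3911 lower in KO, and 5096 were called in the same direction in both genotypes and 98 in opposite directions, with a correlation across genes of 0.739. Annotated pseudogenes took part in the second interval: 221 were higher and 559 lower in KO, against 193 and 109 in WT.

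At 0 h, before stimulation, 4 genes were higher and 4 lower in KO than in WT. Beside Eomes, the lower genes were Myb, a transcription factor of blood progenitors and developing T cells (5.66 ± 0.569 CPM in KO and 12.1 ± 3.63 in WT, SD, n = 3, log2 fold change -1.10, SE 0.14, adjusted p = 2.51e-04), the potassium channel gene Kcnc1 (1 count in each KO library and 26, 23 and 14 in WT, adjusted p = 0.00311) and Hdac9, a histone deacetylase (-2.30, SE 0.42, adjusted p = 0.0270). The higher genes were Tnfsf4, which encodes the costimulatory OX40 ligand (1.05 ± 0.173 and 0.136 ± 0.0414 CPM, log2 fold change 2.93, SE 0.37, adjusted p = 1.76e-04), Phlda3, a p53 target that restrains AKT (1.46 ± 0.276 and 0.276 ± 0.0880 CPM, 2.38, SE 0.29, adjusted p = 1.08e-04), Psrc1, which encodes a spindle protein (0.750 ± 0.108 and 0.111 ± 0.0367 CPM, 2.72, SE 0.33, adjusted p = 1.08e-04) and Gm33707. Gm33707 (ENSMUSG00000102298, chromosome 3, 60769887 to 60770455) is annotated as a processed pseudogene and was at 8.24 ± 2.25 CPM in KO and 0.182 ± 0.117 in WT (log2 fold change 5.50, SE 0.32, adjusted p = 3.91e-10). It fell outside the rule for named genes and was chosen after its values were seen. Except for Myb, Eomes and Gm33707, all of these genes lay below 2 CPM in both groups, with 1 to 62 counts per library.

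Of the other genes that the rule names at 0 h, Pigyl (8.14 ± 1.26 CPM in KO, 4.99 ± 0.182 in WT), Bola2 (40.8 ± 8.68 and 27.9 ± 1.21) and Fzd3 (0 counts in KO, 0.123 ± 0.0173 CPM in WT) had the smallest p beyond the called ones, and each had adjusted p = 0.0748. Respiratory and ribosomal genes stood slightly higher in KO without passing the test over all genes. Of 36 complex I subunits 0 passed (22 higher adjusted over the list alone, median 0.22), of 24 subunits of complexes II to IV 0 passed (11 higher adjusted over the list alone, median 0.18), and of 86 cytosolic ribosomal protein genes 0 passed (60 higher adjusted over the list alone, median 0.25). Adjusted p with an estimated correlation was 0.265, 0.265 and 0.305. Ribosomal protein genes took 12.3% ± 1.97 of counts in KO and 10.5% ± 0.582 in WT (SD, n = 3, exact two-sided permutation p = 0.3, smallest possible 0.1). The difference of 1.82 points became 0.865 without KO replicate 2 and 2.83 without KO replicate 1. That library, at 10.3%, lay within the WT range of 9.99% to 11.1%. Of the T-box list, 1 of 4 genes, Eomes itself, was lower, and the list gave adjusted p = 0.0389 with an estimated correlation. By edgeR 1771 genes had an unadjusted p under 0.05, and 8.17% of genes had groups that did not overlap, where chance gives 10%. The count for KO vs WT at 0 h, 8, became 660 without KO replicate 1 and 13 without WT replicate 3, 53 by DESeq2 and 2 when only the 0 h libraries were fitted.

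**Figure D3:**
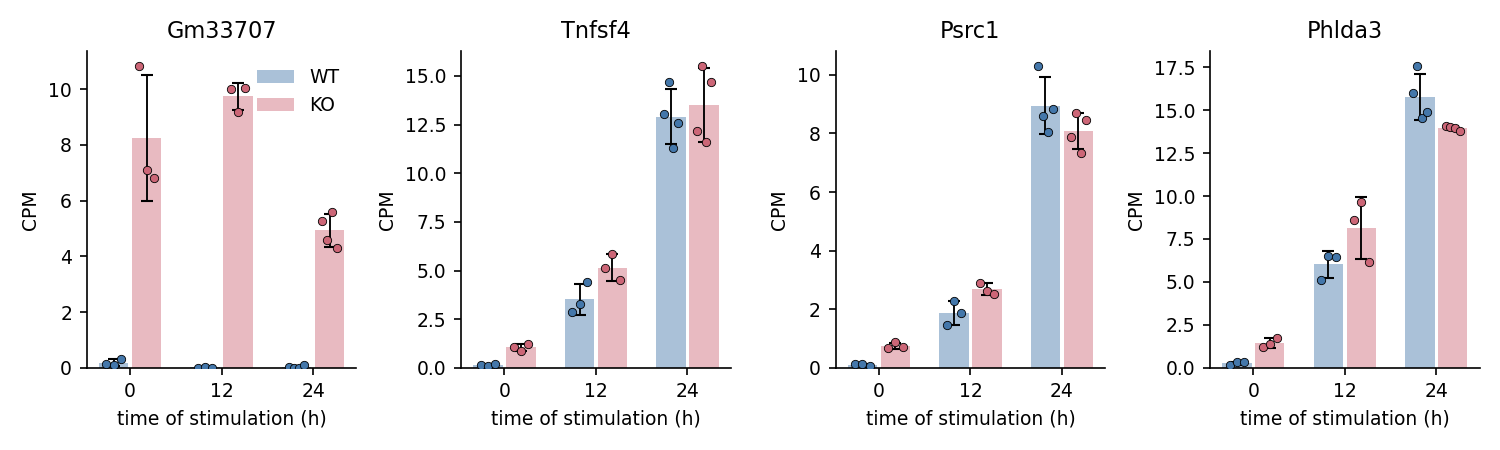
Expression of Gm33707, Tnfsf4, Psrc1 and Phlda3 in CPM (y axes, from 0) by time and genotype (x axes), with bars for group means, error bars for SD and points for libraries. Gm33707 stood at 8.24, 9.74 and 4.94 in KO at 0, 12 and 24 h against 0.182, 0.0122 and 0.0286 in WT, while Tnfsf4, Psrc1 and Phlda3 reached similar levels in both genotypes at 24 h.

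At 12 h, 2 genes were higher in KO than in WT and 1, Eomes, was lower. Gm33707 was at 9.74 ± 0.483 CPM in KO, with 302 to 330 counts per library, and had 1 count in the 3 WT libraries together (adjusted p = 1.07e-11). Gm38326 (ENSMUSG00000103587, chromosome 3, 60788361 to 60794730), annotated as a long intergenic noncoding RNA on the same stretch of chromosome 3, was at 0.864 ± 0.107 CPM in KO (SD, n = 3), with 25 to 32 counts per library, and had 0 counts in every WT library (adjusted p = 8.07e-05). Both were chosen after their values were seen. At 24 h Gm33707 was at 4.94 ± 0.592 CPM in KO and 0.0286 ± 0.0399 in WT, and Gm38326 at 1.07 ± 0.228 and 0.00706 ± 0.0141 (SD, n = 4).

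The genes with the smallest p beyond these at 12 h did not pass the test. Xcl1 was at 116 ± 5.44 CPM in KO and 64.7 ± 24.3 in WT (adjusted p = 0.194), mt-Rnr2, a mitochondrial ribosomal RNA, at 826 ± 56.0 and 613 ± 58.1 (adjusted p = 0.126), Rrm2 at 8.30 ± 0.195 and 6.22 ± 0.681 and Fam162a at 59.0 ± 5.95 and 46.9 ± 2.24 (both adjusted p = 0.324). Lower in KO were Fcho2, of the endocytic machinery, at 29.2 ± 1.30 and 39.8 ± 3.46 CPM (adjusted p = 0.126), Gucy1b1 at 1.55 ± 0.190 and 2.71 ± 0.308 (adjusted p = 0.141), Pigr at 0.0516 ± 0.0344 and 0.656 ± 0.442 (adjusted p = 0.0818) and Fcgr2b at 0.0661 ± 0.114 and 1.51 ± 1.31 (adjusted p = 0.161). Dnm3 was at 0.221 ± 0.0730 and 0.0122 ± 0.0211 CPM (adjusted p = 0.309). Of 25 activation genes 0 passed, also adjusted over the list alone, with a median of 0.28, and of 28 ribosome biogenesis genes 0 passed, also over the list alone, with a median of 0.14 (adjusted p = 0.394 with an estimated correlation for both). By edgeR 1475 genes had an unadjusted p under 0.05, and the groups did not overlap in 16.7% of genes, where chance gives 10%. The count for KO vs WT at 12 h, 3, became 9 without WT replicate 2, 7 without WT replicate 3, 12 by DESeq2 and 1 when only protein-coding genes were tested.

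At 24 h the genotypes differed broadly, and subunits of the respiratory chain were among the genes lower in KO. A batch made up of the 4 KO libraries at 24 h cannot be told apart from genotype. This limit holds for every difference at 24 h and for differences between genotypes in the changes up to 24 h. Of 36 nuclear subunits of complex I, the entry point of electrons into the chain, 22 fell and 1, Ndufs4, rose (24 and 1 adjusted over the list alone), with a median log2 fold change of -0.27 and adjusted p = 0.943 with an estimated correlation. Ndufa3 was at 33.1 ± 3.21 CPM in KO and 53.7 ± 1.21 in WT (SD, n = 4, log2 fold change -0.70, SE 0.10, adjusted p = 1.48e-04). Ndufa12 and Ndufc1 each changed by -0.57 (SE 0.09 and 0.10). Of 24 subunits of complexes II to IV 12 fell and 0 rose (13 and 0 adjusted over the list alone), with a median of -0.22 and adjusted p = 0.943 with an estimated correlation. Among these, the cytochrome oxidase subunits Cox8a (36.4 ± 5.40 and 71.2 ± 5.01 CPM, -0.96, SE 0.13, adjusted p = 8.35e-05), Cox5b (-0.90, SE 0.13) and Cox7c (-0.57, SE 0.08) fell. Of 16 ATP synthase genes 6 fell and 0 rose (7 and 0 adjusted over the list alone, adjusted p = 0.943 with an estimated correlation), led by Atp5k (27.2 ± 3.19 and 59.0 ± 2.39 CPM, -1.11, SE 0.16, adjusted p = 1.30e-04). With a trend in transcript length and GC content removed from each library, 12, 8 and 4 members of these lists fell and 2, 2 and 0 rose. Atp5g2 turned from -0.37 to 0.11 while Atp5d, at -0.31 before, was no longer called at -0.06.

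Some genes of mitochondrial translation and import were lower in KO at 24 h, and most of each list did not pass. Of 84 genes of mitochondrial translation 23 fell and 0 rose in KO (26 and 2 adjusted over the list alone, adjusted p = 0.943 with an estimated correlation), among them the ribosomal proteins Mrpl34 (9.84 ± 1.40 CPM in KO and 19.7 ± 1.29 in WT, adjusted p = 1.28e-04), Mrpl57 (-0.86, SE 0.14) and Mrps36 (-0.63, SE 0.09). Of 33 import and chaperone genes 7 fell and 0 rose (8 and 0 adjusted over the list alone, adjusted p = 0.943 with an estimated correlation), among them Tomm7 (-0.59, SE 0.10) and Timm23 (-0.55, SE 0.10), parts of the outer and inner membrane translocases. Romo1, a small inner membrane protein, fell from 23.4 ± 1.85 CPM in WT to 9.52 ± 2.79 in KO (-1.28, SE 0.20). Ndufaf8, a complex I assembly factor, changed by -1.19 (SE 0.20). Of the 13 protein-coding genes of the mitochondrial genome 4 rose and 2 fell (6 and 2 adjusted over the list alone, adjusted p = 0.943 with an estimated correlation), among them mt-Co1 (0.33, SE 0.06, adjusted p = 0.00133) and mt-Atp8 (-0.61, SE 0.15, adjusted p = 0.00638, not called with the length trend alone removed). Mitochondrial transcripts took 3.27% ± 0.112 of all counts in KO and 2.82% ± 0.203 in WT (SD, n = 4). Each KO library lay above each WT library (exact two-sided permutation p = 0.0286, the smallest possible, 0.171 adjusted over 18 tests).

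**Figure D4:**
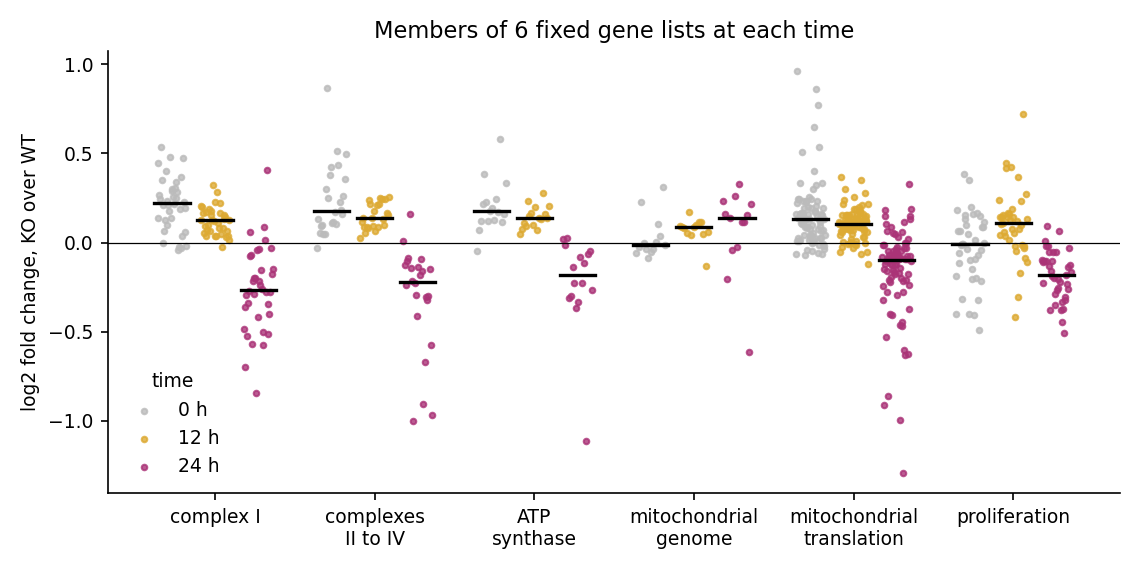
Log2 fold change of KO against WT (y axis) for each measured member of 6 gene lists at 0, 12 and 24 h (x axis). Each point is a gene and each black line the median of its list, which for complex I was 0.22 at 0 h, 0.12 at 12 h and -0.27 at 24 h.

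Some genes of the cell cycle and of ribosomes were lower in KO at 24 h, and these lists did not pass the test against other genes. Of 39 genes of DNA replication and mitosis 13 fell and 0 rose (17 and 0 adjusted over the list alone), with a median of -0.18 and adjusted p = 0.943 with an estimated correlation. Cdt1, which licenses replication origins, was at 72.7 ± 2.27 CPM in KO and 94.4 ± 4.68 in WT (SD, n = 4, -0.38, SE 0.06, adjusted p = 3.52e-04). Ccnb1, the cyclin of mitotic entry, changed by -0.38 (SE 0.08) and Birc5, which encodes survivin, by -0.42 (SE 0.10). Of 28 ribosome biogenesis genes 2 fell and 0 rose (5 and 1 adjusted over the list alone, adjusted p = 0.943 with an estimated correlation), the nucleolar Fbl (-0.54, SE 0.07, adjusted p = 3.97e-05) and Gar1 (-0.64, SE 0.08). Of 86 cytosolic ribosomal protein genes 46 fell and 2 rose (58 and 2 adjusted over the list alone), with a median of -0.26 and adjusted p = 0.984 with an estimated correlation. They took 7.71% ± 0.335 of counts in KO and 9.09% ± 0.359 in WT (exact two-sided permutation p = 0.0286, the smallest possible, 0.171 adjusted over 18 tests). Without the length and GC trend 30 of the 86 fell and 6 rose.

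Among genes ranked by size, with a mean of at least 5 CPM in 1 group, the largest falls at 24 h were of 2 RNAs that are not messenger RNAs. These were mt-Tc, the mitochondrial cysteine tRNA (-2.68, SE 0.36, and -2.15 with the length and GC trend removed), and Rpph1, the RNA of ribonuclease P (-2.19, SE 0.35, and -1.39 with the trend removed). Next came Jund, an AP-1 transcription factor, at 9.85 ± 1.55 CPM in KO and 28.8 ± 4.02 in WT (-1.54, SE 0.23, adjusted p = 1.46e-04). Its relative Junb was at 22.2 ± 6.28 and 55.3 ± 5.48 CPM (-1.30, SE 0.33, adjusted p = 0.00947). Tmsb10, which binds actin monomers, was at 252 ± 23.6 and 641 ± 26.2 CPM (-1.34, SE 0.20). Crlf2, a receptor chain for thymic stromal lymphopoietin, was at 3.32 ± 1.12 and 9.17 ± 0.777 (-1.43, SE 0.29). With the length and GC trend removed, Jund was at -0.98, Junb at -0.97, Tmsb10 at -1.02 and Crlf2 at -0.94, all still called. Slc7a11, the cystine transporter that feeds glutathione synthesis, was at 0.151 ± 0.0532 and 1.21 ± 0.139 CPM (-2.91, SE 0.45, adjusted p = 2.24e-04), one of 6 antioxidant genes of 26 that fell against 1 that rose (6 and 1 adjusted over the list alone, adjusted p = 0.943 with an estimated correlation). Sod1, the cytosolic superoxide dismutase, changed by -0.38 (SE 0.07). With the length and GC trend removed 2 antioxidant genes fell and 3 rose, and Slc7a11 stayed at -3.06.

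Fewer genes were higher in KO at 24 h, and by less. Ahnak, a large scaffold protein, changed by 0.81 (SE 0.17, n = 4, adjusted p = 0.00232) from 58.0 ± 3.53 CPM in WT. Foxp3, the factor that defines regulatory T cells, was at 6.93 ± 1.37 and 4.01 ± 0.817 CPM (0.77, SE 0.20, adjusted p = 0.0118), 1 of 2 regulatory T cell genes of 14 that rose while 0 fell (2 and 1 adjusted over the list alone, adjusted p = 0.943 with an estimated correlation). Mbnl1, a splicing regulator on chromosome 3 at 60472830 to 60629750, was at 1273 ± 139 and 868 ± 33.3 CPM (0.55, SE 0.08, adjusted p = 8.44e-05). It lies within 5 megabases of Gm33707, where an inserted transgene or a linked strain segment stays open. Tgfbr1, a TGF-β receptor chain, changed by 0.43 (SE 0.08) and Cxcr6, a chemokine receptor, by 0.49 (SE 0.11). Zfp563 (0.65, SE 0.13), Wdr89 (0.64, SE 0.16), Psme2b (0.60, SE 0.11), Prss12 (0.59, SE 0.13), Acvr2a (0.56, SE 0.13), Crebrf (0.54, SE 0.11) and Ilk (0.64, SE 0.17, not called without KO replicate 3) completed the ranked genes that rose.

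Lists of survival and helper cell fate held few to several called genes in KO at 24 h, and each list of survival, helper fate, cytokines or cytokine receptors gave adjusted p = 0.943 with an estimated correlation. Of 26 pro-apoptotic genes 1 fell, the BH3-only gene Bbc3 (5.98 ± 0.531 CPM in KO, 10.4 ± 0.770 in WT, -0.79, SE 0.15, adjusted p = 0.00125), which was not called at -0.33 with the length and GC trend removed (adjusted p = 0.0593). Of 16 anti-apoptotic genes 1 fell, Birc5. Of 13 Th1 genes 1 rose (Cxcr6), of 9 Th2 genes 1 fell (Gata3, -0.46, SE 0.11) and of 18 cytokine genes 1 fell (Tgfb1, -0.45, SE 0.09). Of 11 Th17 genes 2 rose and 0 fell, Tgfbr1 and Il6st, a shared receptor chain of the interleukin-6 family (0.32, SE 0.09, not called without WT replicate 2 or KO replicate 3). All these counts were the same adjusted over the list alone. Of 38 interferon-stimulated and 16 coinhibitory genes 0 passed, also adjusted over the list alone. Of 23 genes of common gamma chain cytokine receptors and memory 5 rose and 3 fell (6 and 3 adjusted over the list alone), among them the receptor chain Il2rg (0.24, SE 0.06) and Socs1, which restrains cytokine signalling (-1.07, SE 0.22). Without 1 WT or KO library, 1 to 3 of the memory list rose.

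In all, 654 genes were higher and 1503 lower in KO at 24 h (14.0% of those tested), of which 35 and 403 by more than a fold of 2, and the median size of a called change was 0.38. Of these, 505 higher and 994 lower genes were protein-coding, and 95 and 385 were annotated pseudogenes. The groups did not overlap in 28.2% of genes, where chance gives 2.86%. Markers of other cells were summed without a test. B cell markers came to 431 ± 35.3 CPM in KO and 426 ± 10.5 in WT, macrophage and monocyte markers to 92.0 ± 5.38 and 81.5 ± 3.46, and CD8 T cell markers to 10.3 ± 1.11 and 7.74 ± 1.07 (SD, n = 4). Most of each sum was 1 gene, with Ighm at 421 and 415 CPM, Ctss at 83.6 and 73.0 and Cd8b1 at 9.89 and 7.42. The sums thus do not measure the share of those cells. With the length and GC trend removed 719 genes were higher and 998 lower, 1180 of them called in the same direction as before. Of the genes then called, 420 higher and 637 lower were protein-coding, and 213 and 280 were annotated pseudogenes, a more even split than before. The splits were 949 and 1184 with the length trend alone and 1038 and 1524 by DESeq2. The count for KO vs WT at 24 h, 2157, became 4083 when only the 24 h libraries were fitted, 1370 without WT replicate 2 and 1418 without WT replicate 4.

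The list test asks whether a list moved more than other genes. With the correlation between genes preset at 0.01, 13 of 34 biological lists passed in KO against WT at 0 h, 17 at 12 h and 7 at 24 h, and 21 and 10 passed in WT from 0 to 12 h and from 12 to 24 h. With an estimated correlation, the lists called in these comparisons were the T-box list at 0 h and the list of DNA replication and mitosis in WT from 12 to 24 h. The T-box list has 4 tested genes, of which only the deleted gene Eomes was called. At 0 h 0 lists were called with a replicate block or when any 1 library other than WT replicate 3 was left out, and 6 were called without that replicate. A test of whether a list's genes moved one way on balance (fry) gave 3 lists at 24 h, all lower in KO: complex I (adjusted p = 0.0134), complexes II to IV (adjusted p = 0.0130) and DNA replication and mitosis (adjusted p = 0.0110).

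The test of whether the response to stimulation differed between genotypes gave different numbers for the 2 intervals. From 0 to 12 h, the log2 change was lower in KO in 4 genes and higher in 0: Tnfsf4 (-2.40, SE 0.42), Psrc1 (-2.20, SE 0.38), Phlda3 (-1.95, SE 0.33) and Phldb1 (-1.21, SE 0.21), each with adjusted p = 0.0337. Their levels at 12 h were not lower in KO for the first 3. Tnfsf4 was at 0.136 ± 0.0414 CPM at 0 h and 3.52 ± 0.797 at 12 h in WT, and at 1.05 ± 0.173 and 5.15 ± 0.671 in KO (SD, n = 3). Psrc1 was at 0.111 ± 0.0367 and 1.87 ± 0.395 CPM in WT and at 0.750 ± 0.108 and 2.68 ± 0.201 in KO. Phlda3 was at 0.276 ± 0.0880 and 6.03 ± 0.774 CPM in WT and at 1.46 ± 0.276 and 8.16 ± 1.80 in KO, so the smaller log2 change went with a higher level at 0 h. All 4 calls ended with limma voom and with the length and GC trend removed, where the log2 values stayed at -2.40 for Tnfsf4, -2.16 for Psrc1, -1.75 for Phlda3 and -1.11 for Phldb1 and only the threshold was missed (adjusted p = 0.0621, and 0.230 for Phlda3). By edgeR 898 genes had an unadjusted p under 0.05, and the count ranged from 0 to 10 without 1 library.

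From 12 to 24 h, 552 genes changed more upward and 1089 more downward in KO than in WT. Subunits of complex I were among the latter, 19 lower and 0 higher of 36 (24 and 0 adjusted over the list alone, median -0.36), as were those of complexes II to IV, 13 and 0 of 24 (17 and 0 adjusted over the list alone), genes of mitochondrial translation, 24 and 0 of 84 (29 and 1 adjusted over the list alone), and genes of DNA replication and mitosis, 9 and 0 of 39 (13 and 0 adjusted over the list alone). Adjusted p with an estimated correlation was 0.612 for these lists except mitochondrial translation, at 0.620. These list counts are those before the length and GC trend was removed, which lowered the counts of the respiratory lists in KO against WT at 24 h. With that trend removed, 534 of all genes changed more upward and 741 more downward. Genes that the naming rule leaves out, some with smaller p, are not given. Among the genes it admits, the smallest p on the lower side was that of mt-Tl1, a mitochondrial leucine tRNA (-3.06, SE 0.34, adjusted p = 7.17e-05). H2afx, the histone that marks DNA breaks (-1.02, SE 0.12), Nutf2, a nuclear import factor (-0.83, SE 0.11), Smco4 (-1.02, SE 0.15), Rilpl2 (-0.73, SE 0.10) and Mrps36 (-0.90, SE 0.13) came next. On the higher side the smallest p were those of Fcho2 (0.74, SE 0.12), the histone demethylases Kdm7a (0.65, SE 0.11) and Kdm5b (0.50, SE 0.08), Bmt2 (0.84, SE 0.14), Acbd5 (0.60, SE 0.10) and Prss12 (1.14, SE 0.20). With the length and GC trend removed the lower genes, in this order, were at -2.31, -0.62, -0.60, -0.75, -0.73 and -0.62. The higher were at 0.58, 0.41, 0.35, 0.68, 0.47 and 1.23, and all stayed called. The splits of higher and lower were 843 and 971 with library size alone and 612 and 764 with the length trend removed. The count of 1641 became 2812 when only the groups compared were fitted and 924 without KO 12 h replicate 2.

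From 0 to 24 h, 562 genes changed more upward and 1384 more downward in KO, of them 25 and 0 of 36 complex I subunits in the downward direction (26 and 1 adjusted over the list alone, adjusted p = 0.529 with an estimated correlation). This list count too is that before the length and GC trend was removed. Myb, lower in KO at 0 h, rose more in KO (1.24, SE 0.17, adjusted p = 1.52e-04), and it was at 73.2 ± 4.12 CPM in KO and 66.4 ± 2.53 in WT at 24 h (SD, n = 4). The change of Eomes differed as well (1.51, SE 0.44, adjusted p = 0.0257, not called with limma voom, or when any 1 of 5 of the libraries was left out). Psrc1 (-2.86, SE 0.35), Phlda3 (-2.55, SE 0.31), Ccdc85b (-2.50, SE 0.33), Tmem160 (-1.59, SE 0.20), Smco4 (-1.18, SE 0.15) and Nutf2 (-0.93, SE 0.11) were the downward genes with the smallest p among those that the naming rule admits. Fam126b (0.79, SE 0.14), Map3k2 (0.60, SE 0.11), Zfp709 (0.60, SE 0.11), Kdm7a (0.59, SE 0.11) and Zfp26 (0.57, SE 0.11) followed Myb among the upward ones. With the length and GC trend removed the downward genes, in this order, were at -2.75, -1.95, -2.51, -0.74, -0.80 and -0.66. The upward genes after Myb were at 0.51, 0.30, 0.39, 0.31 and 0.26, and all stayed called. The splits were 932 and 1269 with library size alone, 963 and 1407 by DESeq2 and 623 and 896 with the length trend removed. The count of 1946 became 1290 with the length and GC trend removed and 1001 without KO 0 h replicate 2.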

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

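The tests of length and GC content and of a library batch at 24 h, and the test of pseudogenes matched on expression, were chosen after the result was seen. Comparisons, lists and the rule for named genes were chosen before the data were examined, as were the alternatives other than those named as added later where the dependence on processing is described.

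In 6 of 172 groups of 4 libraries, 1 library lay far from the other 3 of its group, where chance alone gives about 1 in 20 groups. In KO at 24 h, Il6st was at 280.2 CPM in replicate 3 and 252 to 254 in the others. Mbnl1 was at 1481 CPM in KO replicate 1 and 1190.1 to 1217 in the others, and Socs1 at 2.04 in the same library and 2.53 to 2.58 in the others. Foxo1 was at 180.4 CPM in KO replicate 1 and 159.6 to 162 in the others. In WT at 24 h, Ccnb1 was at 37.6 CPM in replicate 1 and 41.1 to 41.7 in the others, and Jund at 34.8 in replicate 2 and 26.4 to 27.4 in the others.

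The change from 0 to 12 h differed between genotypes in 4 genes, Tnfsf4 (-2.40), Phlda3 (-1.95), Phldb1 (-1.21) and Psrc1 (-2.20). That from 12 to 24 h differed in 1641 genes. Among those that the naming rule admits, the smallest p on the lower side were those of Nutf2 (-0.83), Rilpl2 (-0.73), H2afx (-1.02), Smco4 (-1.02), Mrps36 (-0.90) and mt-Tl1 (-3.06). On the higher side these were Acbd5 (0.60), Prss12 (1.14), Fcho2 (0.74), Kdm5b (0.50), Kdm7a (0.65) and Bmt2 (0.84). That from 0 to 24 h differed in 1946 genes, among them Nutf2 (-0.93), Tmem160 (-1.59), Phlda3 (-2.55), Smco4 (-1.18), Psrc1 (-2.86) and Ccdc85b (-2.50), and Myb (1.24), Eomes (1.51), Map3k2 (0.60), Fam126b (0.79), Kdm7a (0.59), Zfp709 (0.60) and Zfp26 (0.57).

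Other splits of the same samples were tried for each count. For KO against WT at 24 h, 1 of 35 splits, the real one, gave as many as 2157 genes, and the highest of the others gave 1. The real split also gave the most for WT from 12 to 24 h (1 of 35, 7356 genes, highest other 3518), KO over the same interval (1 of 35, 8286, highest other 5152), and the differences between genotypes from 12 to 24 h (1 of 100, 1641, highest other 79) and from 0 to 24 h (1 of 100, 1946, highest other 5). These are the smallest shares that so many splits can give. Splits that mix groups which differ also widen the fitted spread, which lowers their counts. The splits alone thus do not exclude chance, and a batch that follows the groups would give the same shares. For the difference from 0 to 12 h, 20 of 100 splits gave 4 or more genes and the highest other 369, so chance is not excluded and the high count points to a structure of the samples. With 3 against 3 the splits are too few for a share under 0.05: KO against WT gave 8 genes at 0 h (highest other 572, as many or more in 3 of 10) and 3 at 12 h (highest other 1), and 12 h against 0 h gave 10642 in WT (highest other 0) and 10935 in KO (highest other 1). The split with 572 set WT replicates 2 and 3 and KO replicate 1 against the others, which points to a structure of the 0 h samples.

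The first pattern weighed was the broad difference at 24 h, including its pseudogenes. With the fitted trend in transcript length and GC content removed, 1180 of 2157 genes were called in the same direction, and 973 were called only with the trend in place. The trend was fitted on the longest annotated transcript of each gene and can leave part of such a bias behind. These calls thus do not exclude length or GC content as the whole cause. Reads shared between genes are argued against as the whole cause for coding genes, of which 11.9% of those sharing no sampled word were called, near the 12.6% of all, though 20.3% of the 443 sharing 0.5 or more were called. For the pseudogenes shared reads may account for part of the calls: 29.6% of those sharing 0.5 or more of their words were called and 29.5% when matched on expression, against 11.4% of 70 that shared none, though 39.6% of those sharing less were called. A batch of the 4 KO 24 h libraries cannot be told apart from genotype: numbers in the labels, whose meaning is not given, part the genotypes at 24 h (KO 267 to 276, WT 279 to 282) but also at 12 h (KO 309 to 329, WT 299 to 304), where 3 genes were called, and over processed pseudogenes their levels correlated at 0.950 with WT 24 h, against 0.990 between genotypes at 0 h and at 12 h and 0.996 over coding genes at 24 h.

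The second pattern was Gm33707 and Gm38326 on chromosome 3, near absent in WT and present in KO at 12 and 24 h. Shared reads are argued against among annotated transcripts, since 0 of 38 sampled words of Gm38326 and 0 of 32 of Gm33707 were shared (0%). An inserted transgene or a linked strain segment could give such a signal and stays open. Of 36 neighbours within 5 megabases 6 moved one way at all 3 times, where random lists gave a median of 6 and a 95th percentile of 10. The bound written beforehand, that a count at the random median would exclude this, was wrong, since an insertion need not move its neighbours. Of the same 36 neighbours 0 were called at 0 h, 0 at 12 h and 7 at 24 h, where 14.0% of all tested genes were called. Mbnl1, higher in KO at 24 h, was among these 7. A biological effect of losing Eomes was not tested apart from an insertion or a linked segment.

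The third pattern was the higher level of Phlda3, Psrc1 and Tnfsf4 in KO at 0 h. RNA or cells of the 24 h samples in these libraries are argued against. The test took 33 genes near absent in WT at 0 h and at 20 CPM or more in WT at 24 h. Their median gain in KO was -0.0586% of the 24 h level, against 8.47% for Phlda3, 7.90% for Psrc1 and 6.76% for Tnfsf4. RNA or cells of the 12 h samples were not tested for. Other technical causes of this pattern were not tested, and an effect of genotype on unstimulated cells stays open as a hypothesis.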

How the results depend on the processing

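The length and GC corrections, the tests without pseudogenes or on coding genes alone, and the test without KO 0 h replicate 1 with the correction were chosen after the data had been seen. Except where a cause is given, the cause was not tested. The 8 genes at 0 h became 521 with no filter, 53 by DESeq2, 2 with only the groups compared, 13 with a replicate block and 327 without KO replicate 1 with the correction. The 3 at 12 h became 175 with no filter, 12 by DESeq2 and 1 among coding genes, where Gm33707 and Gm38326 are not tested. With no filter the fit gave no gene a variance of its own, so its added calls are not evidence of more changes. The 2157 at 24 h became 4083 and the 1641 from 12 to 24 h 2812 with only the groups compared, and the 1946 from 0 to 24 h became 1290 with the length and GC correction. The 4 from 0 to 12 h became 97 with no filter and 0 with limma voom, only the groups compared, a replicate block, either the full or the GC correction, and coding genes alone. With the full correction the log2 values of these 4 genes were -2.40 to -1.11, against -2.40 to -1.21, so these lost calls are not evidence for the trend as their cause.

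Lists called with a preset correlation were 13 at 0 h, 17 at 12 h, 7 at 24 h, 21 and 10 for the WT intervals, and 15, 11 and 7 for the differences between genotypes from 0 to 12, 12 to 24 and 0 to 24 h. By fry they were 3 at 24 h, 34 and 20 for the WT intervals and 8 and 6 for the last 2 differences, and with a replicate block 0 at 0 h. The log2 fold change of Fkbp8, KO vs WT at 24 h, turned from -0.24 to 0.12 with the length and GC correction and 0.16 with GC alone. That of Atp5g2, KO vs WT at 24 h, turned from -0.37 to 0.11 and 0.0459. The pseudogene share at 24 h, 0.120 points higher in KO, became 0.139 without mitochondrial genes (exact permutation p = 0.0571 and 0.0286).

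Leaving out 1 library in turn gave 7 to 660 genes at 0 h, 3 to 9 at 12 h, 1370 to 1968 at 24 h, 9937 to 10663 and 6463 to 6851 for the WT intervals, 10349 to 10763 and 7217 to 7893 for those in KO, and 0 to 10, 924 to 1765 and 1001 to 2635 (without KO 0 h replicate 1) for the differences. Eomes ranged from -3.52 to -3.15, -3.14 to -2.46 and -2.06 to -1.53. Lists called ranged from 0 to 6 at 0 h, 0 to 1 and 1 to 1 for the WT intervals, and 0 to 4 for the difference from 0 to 12 h. KO minus WT shares in points ranged, at 0, 12 and 24 h, from -0.343 to 0.0523, 0.0360 to 0.225 and 0.357 to 0.503 for mitochondrial genes, 0.865 to 2.83, 0.215 to 0.876 and -1.51 to -1.21 for ribosomal proteins, -0.0198 to 0.2698, 0.0262 to 0.228 and 0.354 to 0.4502 for the 10 most counted genes, and 0.0710 to 0.265, 0.0849 to 0.152 and 0.0941 to 0.143 for pseudogenes. At 0 h the mitochondrial and 10-gene shares changed sign without WT replicate 1.

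Of 1677 values of named genes at 24 h under alternatives, 1539 kept direction and side of the threshold, 134 lost the call and 4 reversed. The labels do not say that replicate numbers pair samples. To look for pairs, the log2 CPM of each library were taken as deviations from its own group mean, not as whole profiles. Correlations of these deviations between WT and KO libraries with the same number ran from -0.247 to 0.0276 at 0 h, -0.146 to 0.0864 at 12 h and 0.0632 to 0.178 at 24 h. By this measure 0 of 6, 1 of 6 and 6 of 8 libraries correlated best with their own number. A pairing at 24 h is thus not excluded, and the replicate block gave 1917 genes there.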

Other observations

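Genes of helper T cell fates moved in several directions in WT. From 0 to 12 h Maf rose from 2.36 ± 0.802 to 49.3 ± 9.44 CPM (SD, n = 3), and Ccr4, a chemokine receptor of Th2 and regulatory cells, from 1.89 ± 0.983 to 24.5 ± 4.21. Gata3, the main Th2 factor, fell from 30.5 ± 2.08 to 8.64 ± 2.05 CPM, and Il4ra, which encodes the interleukin-4 receptor, changed by -1.32 (SE 0.07). Of 9 Th2 genes 5 rose and 2 fell (adjusted p = 0.473 with an estimated correlation), and of 11 Th17 genes 5 rose and 4 fell (adjusted p = 0.375 with an estimated correlation). Of 23 trafficking genes 7 rose and 11 fell, among them the gut-homing receptors Ccr9 (-3.22, SE 0.21) and Itgb7 (-2.17, SE 0.10), with adjusted p = 0.659 with an estimated correlation. All these counts were the same adjusted over the list alone.

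Survival and fuel genes also moved in WT. From 0 to 12 h Bcl2l1, which encodes the survival protein BCL-XL, changed by 1.84 (SE 0.08) and Bcl2l11, which encodes the death protein BIM, by 1.89 (SE 0.10). Of 16 anti-apoptotic genes 8 rose and 4 fell (adjusted p = 0.156 with an estimated correlation), and of 26 pro-apoptotic genes 10 rose and 10 fell (adjusted p = 0.781 with an estimated correlation), with the same counts adjusted over the list alone. From 12 to 24 h 14 pro-apoptotic genes rose and 2 fell, also adjusted over the list alone (adjusted p = 0.292 with an estimated correlation). Of 19 fatty acid oxidation genes 8 fell and 4 rose from 0 to 12 h, also adjusted over the list alone (adjusted p = 0.604 with an estimated correlation). Cpt1a, which admits fatty acids to mitochondria, changed by -1.34 (SE 0.13) and then, from 12 to 24 h, by 0.65 (SE 0.12). Of 23 genes of the citric acid cycle 13 rose and 5 fell by 12 h, also adjusted over the list alone, with adjusted p = 0.803 with an estimated correlation.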
